A study of Arabidopsis thaliana with 36 samples.

How the data were processed

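Whole seedlings of 4 genotypes at 0, 1 and 8 h of simulated shade were sequenced as stranded mRNA libraries in paired-end mode. Per the labels, the authors aligned the reads with STAR 2.5.3a and estimated counts per gene with RSEM 1.3.0 on the TAIR10 assembly of the Arabidopsis genome. The deposited table holds expected_counts per gene and library, all whole numbers, so the estimates had been rounded. The strand setting and the annotation release are not given in the sources used here. The reference used here for gene names, neighbours and transcript sequences is TAIR10.1, so no coordinates are given. Of the 32833 identifiers in the table, 32548 were matched in the reference table, and 5826 genes had 0 counts in every library.

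The 36 libraries form 12 groups of 3 by genotype and time, as the labels give them. Library totals ran from 30846115 to 58025421 counts, and 3 counts in a library was taken as the floor for a group with no counts. Floors cover counting error only. No pair of replicates was a copy of another: the lowest chi-square per degree of freedom between replicates was 3.92.

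Differential expression was tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on all 36 libraries in 1 fit with 12 group terms, TMM scaling and filterByExpr (minimum count 10, minimum total count 15), which left 21562 genes. P values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and genes were called at an adjusted p under 0.05. Tests were 2-sided. The 22 comparisons were shade against 0 h in each genotype at 1 and 8 h, 8 h against 1 h in WT, each mutant against WT at 0 h, the differences between these responses, and the departure of hy5 pif457 from the sum of hy5 and pif457. Standard errors were derived from the fold change and its F statistic. Every 0 h group serves as the control of both times, so overlaps between times are given with the overlap of independent lists and with simulations of unchanged groups, from which lists of the same sizes were taken by rank of p.

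The 25 gene lists cover shade markers, auxin biosynthesis, early auxin response, SAUR genes, brassinosteroid, gibberellin, cytokinin, cell wall loosening, flavonoid, photosynthesis, chlorophyll, carotenoid, light signalling, clock, abscisic acid and cold, jasmonate, salicylate and immunity, nitrate, iron, dark and sugar starvation, cell cycle, heat shock, touch and wounding, root tissue markers and stomatal lineage markers. They hold 503 entries for 494 genes and were written from general knowledge. Each list was tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, with adjustment over all 550 tests. Calls that hold with both are those with both adjusted p under 0.05. The count adjusted over the list alone uses the edgeR p values of the members of that list.

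Genes were named by a rule. HY5, PIF4, PIF5 and PIF7 were named in all groups. In each comparison, called genes with a mean log2 CPM of at least 2, a symbol and, for a comparison of 2 groups, no overlap between their libraries were ranked by fold. The 8 highest and lowest were named for WT against 0 h, 6 each for mutants against WT at 0 h, 5 each for the mutant responses and for response differences from WT, and 3 each otherwise. For a list, up to 4 members with the smallest adjusted p were named, as were those named for WT at the same time. Genes that kept their call with each single library left out were preferred in the text. Of 492 named genes, 23 shared at least 10% of their 50-base stretches with other genes, SAUR19, SAUR62, SAUR63, SAUR67 and several LHCB genes among them, so the values of these genes are uncertain.

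The design, the lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were RLE size factors, DESeq2 (1.42.0), no filter on low counts (27007 genes), a filter of CPM at least 1 in at least 3 samples (19686 genes), a fit of only the groups compared, the replicate number as a block, each library left out in turn, and the estimated correlation. Added after the data were seen were the root marker score as a covariate, the replicate number as a block in fits of 0 and 1 h alone in hy5 and pif457, leaving out 289 rRNA and organelle genes (135 of them tested), and leaving out 12 libraries rich in rRNA. Tested on simulated data with 21167 genes, the comparison of WT at 1 h with 0 h recovered 40.8% of genes with a 1.5-fold change, 79.4% with a 2-fold and 98.4% with a 4-fold change, and called 5 of 20947 unchanged genes. The hy5 response difference at 1 h recovered 15.5%, 67.6% and 90.2%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.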

Results

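RNA-seq libraries of whole 7-day-old Arabidopsis thaliana seedlings measured transcripts before and during simulated shade, which was white light enriched with far-red light. The seedlings had been grown in continuous white light and were sampled at 0, 1 and 8 h of shade. No group was kept in white light until 1 or 8 h. Each shade response therefore also holds any change with elapsed time, which cannot be told apart from shade here. The 4 genotypes were the wild type (WT, Col-0), hy5, pif457 and hy5 pif457. HY5 is a bZIP transcription factor that promotes light-dependent development, and PIF4, PIF5 and PIF7, the factors mutated in pif457, are bHLH transcription factors that promote elongation in shade. Each of the 12 groups held 3 biological replicates. Of the 32833 genes in the table, 21562 passed the filter on low counts and were tested. Levels are given as CPM, counts scaled to the library total after TMM adjustment (mean ± SD, n = 3 libraries per group), and effects as log2 fold changes with their standard error. Genes given as the highest or lowest between a pair of groups had no overlap between their libraries. Members named for a list are among the 4 with the smallest adjusted p of that list in that comparison.

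The mutated genes showed how far each mutant had lost its transcripts. HY5 (AT5G11260) stood at 18.6 ± 2.11 CPM in WT at 0 h and at 27.9% of the WT level in hy5 (log2 fold change -1.84 ± 0.14, edgeR adjusted p = 3.01e-10) and 28.5% in hy5 pif457 (-1.81 ± 0.14, adjusted p = 1.53e-09). PIF5 (AT3G59060) was at 5.2% of WT in pif457 and 6.3% in hy5 pif457 at 0 h, and PIF7 (AT5G61270) at 9.6% and 11%. The PIF4 (AT2G43010) transcript was not lost. It was at 80.9% of WT in pif457 at 0 h (adjusted p = 0.849) and at 50.3% at 8 h (-0.99 ± 0.20, adjusted p = 0.00193). In hy5 pif457 it was at 156.6% of WT at 1 h (adjusted p = 0.0471) and at 66.5% at 8 h (adjusted p = 0.039). Transcript counts do not show whether these alleles make protein. In hy5 at 0 h PIF4 was at 253.3% of WT (1.34 ± 0.20, adjusted p = 0.000113) and PIF5 at 254.2% (1.35 ± 0.21, adjusted p = 0.000142), while PIF7, at 152.7%, did not pass (adjusted p = 0.0732).

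**Figure D1:**
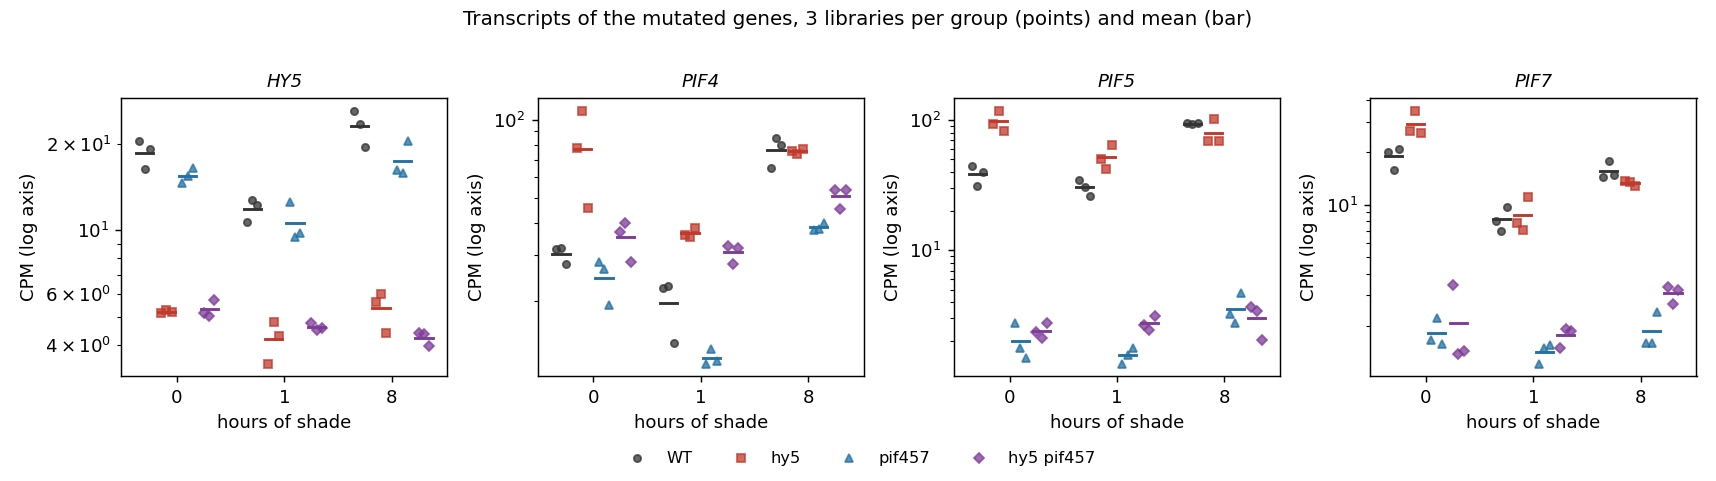
Levels of HY5, PIF4, PIF5 and PIF7 in CPM (log axis) against hours of simulated shade for the 4 genotypes, with each point 1 library and each bar the mean of 3. HY5 is at 27.9% of WT in hy5 at 0 h, PIF5 at 5.2% and PIF7 at 9.6% in pif457, and PIF4 remains at 80.9% there.

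Library composition differed between groups. The share of counts from rRNA genes lay between 6.01% and 11.62% (median 9.28%) in 12 libraries, the 3 of pif457 at 8 h and all 9 of hy5 pif457, and between 0.47% and 2.63% (median 0.72%) in the other 24. These 12 libraries also carry the last sample numbers of the labels. A root marker score, the mean log2 CPM of 23 measured genes typical of root tissue, differed between replicates of a group as well as between groups. It was 1.06 ± 0.323 in WT at 0 h, 1.56 ± 0.749 at 1 h and -0.42 ± 1.64 at 8 h. It was 1.09 ± 0.418, 2.5 ± 0.264 and 1.8 ± 0.078 in hy5 at 0, 1 and 8 h, and 2.35 ± 0.326 in hy5 pif457 at 0 h.

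**Figure D2:**
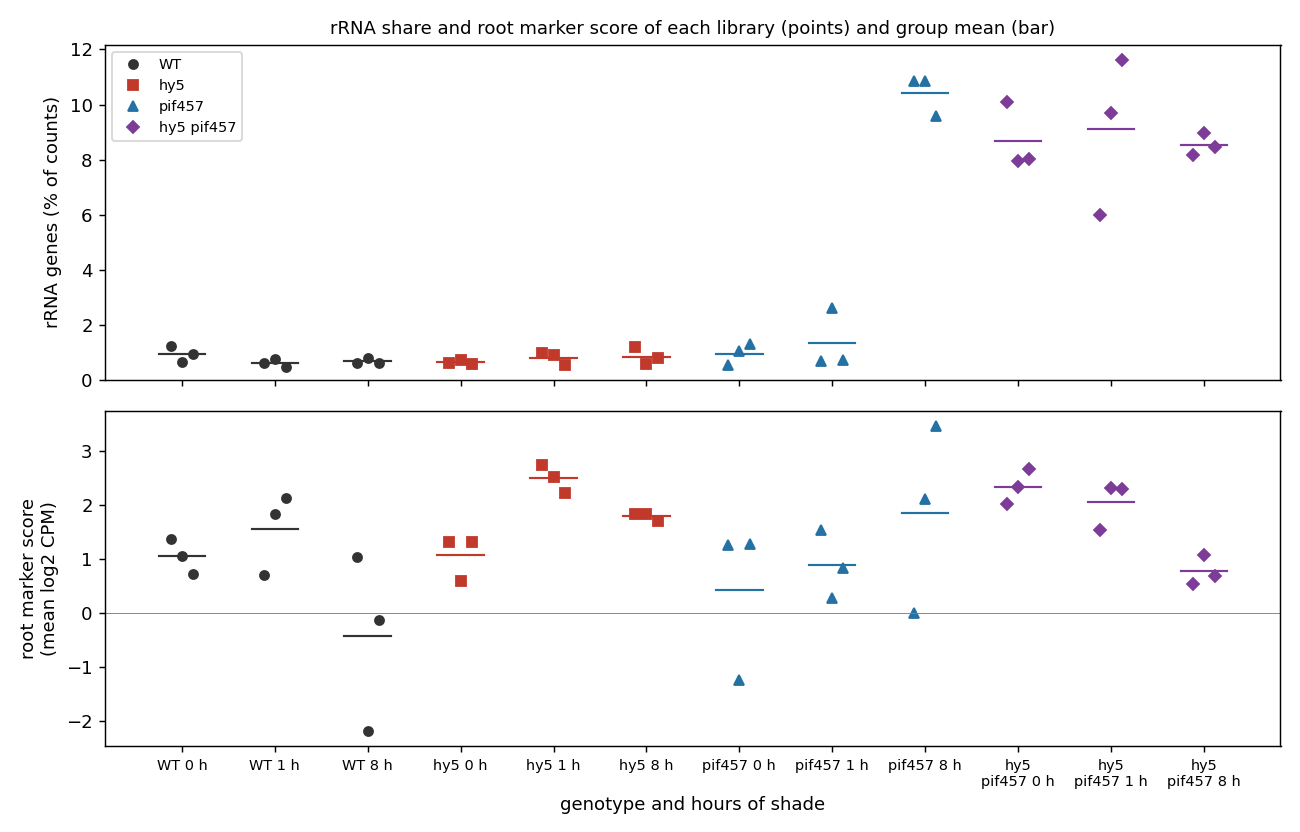
Percent of counts from rRNA genes and root marker score (mean log2 CPM of 23 root tissue markers) for each of the 36 libraries by genotype and hours of shade, with a bar at each group mean. The 3 pif457 libraries at 8 h and the 9 hy5 pif457 libraries lie at 6.01% rRNA or more, and the other 24 at 2.63% or less.

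The comparison of WT at 1 h with 0 h asked which transcripts change early in shade. IAA29 (AT4G32280), an auxin-response repressor, rose from 0.461 ± 0.0914 to 69.8 ± 6.82 CPM (7.24 ± 0.38, adjusted p = 2.03e-13). PIL1 (AT2G46970), a bHLH gene used as a shade marker, rose from 0.415 ± 0.132 to 46.8 ± 6.12 CPM (6.79 ± 0.40), and YUC9 (AT1G04180), which encodes an enzyme of auxin synthesis, from 0.757 ± 0.229 to 42.7 ± 4.25 CPM (5.81 ± 0.43). ATHB2 (AT4G16780), a homeodomain-leucine zipper gene induced by a low ratio of red to far-red light, rose from 5.01 ± 0.502 to 129 ± 1.04 CPM (4.68 ± 0.16, adjusted p = 5.74e-18). The lowest folds included BIC2 (AT3G44450), an inhibitor of cryptochromes (-1.59 ± 0.18), and BBX18 (AT2G21320), a B-box gene (-1.27 ± 0.26). With edgeR, 1121 genes were called, 767 higher and 354 lower. Of the higher genes 241 and of the lower 70 changed at least 2-fold.

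Auxin and growth lists were among those that rose at 1 h. Of the shade markers, 22 of 24 rose (22 adjusted over the list alone; median log2 fold change 3.02; camera adjusted p = 7.33e-58; adjusted p = 8.75e-07 with an estimated correlation). All 18 measured SAUR genes, small auxin-induced growth genes, rose (18 adjusted over the list alone; median 3.14), with SAUR23 (AT5G18060) at 4.53 ± 0.31 (camera adjusted p = 1.08e-56, and adjusted p = 0.000275 with an estimated correlation). Early auxin response genes rose at 18 of 22 members (20 adjusted over the list alone), such as IAA19 (AT3G15540, 3.98 ± 0.33) and IAA2 (AT3G23030, 2.73 ± 0.21), with camera adjusted p = 5.46e-41, and adjusted p = 4.81e-05 with an estimated correlation. Among auxin biosynthesis genes YUC8 (AT4G28720, 4.09 ± 0.38) and YUC2 (AT4G13260, 1.47 ± 0.21) rose, 4 higher and 1 lower of 10 (4 and 1 adjusted over the list alone). This call was lost in the stricter test (camera adjusted p = 0.0123, and adjusted p = 0.0661 with an estimated correlation). The gibberellin list had 6 of 15 members higher (8 higher and 1 lower adjusted over the list alone), among them the synthesis genes GA20OX1 (AT4G25420, 3.14 ± 0.40) and GA20OX2 (AT5G51810, 2.17 ± 0.29) and the repressor gene GAI (AT1G14920, 1.12 ± 0.11), with camera adjusted p = 0.000186, and adjusted p = 0.00406 with an estimated correlation. The photoreceptor gene PHYB (AT2G18790) rose (1.58 ± 0.15), within a light signalling list that had 7 higher and 5 lower of 41 measured, 10 and 11 adjusted over the list alone (camera adjusted p = 0.749, and adjusted p = 0.931 with an estimated correlation).

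Further lists were tested at 1 h. The brassinosteroid list had 5 higher and 1 lower of 11 measured, 5 and 1 adjusted over the list alone, with the inactivating enzyme gene BAS1 (AT2G26710) at 2.62 ± 0.16 and the synthesis gene DWF4 (AT3G50660) at 0.86 ± 0.09 (camera adjusted p = 0.000316, and adjusted p = 0.107 with an estimated correlation). In the cytokinin list CKX5 (AT1G75450, 2.81 ± 0.33) and CKX6 (AT3G63440, 2.21 ± 0.19), both cytokinin-degrading oxidase genes, rose, 2 higher and 0 lower of 16 measured, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.159 with an estimated correlation). The clock list tended lower with a median of -0.29 and 1 of 23 members called (8 adjusted over the list alone; camera adjusted p = 0.00048; adjusted p = 0.0909 with an estimated correlation). The iron list had 1 of 19 higher (2 adjusted over the list alone; camera adjusted p = 0.0272; adjusted p = 0.64 with an estimated correlation). In the heat shock list 3 of 10 were higher (4 adjusted over the list alone; camera adjusted p = 0.0315; adjusted p = 0.439 with an estimated correlation). Nitrate uptake and assimilation genes had no member called by edgeR among 13 (0 adjusted over the list alone), a median of 0.28 and camera adjusted p = 0.307, and this list passed in none of the 22 comparisons. HY5 itself fell at 1 h (-0.65 ± 0.13), as did PIF7 (-1.2 ± 0.22). The count of 1121 was 329 in a fit of the compared groups alone and 738 without the 12 libraries rich in rRNA. It was 518 without WT 0 h replicate 1, 2484 without its replicate 2, 509 without its replicate 3, 698 without WT 1 h replicate 1, 673 without its replicate 2 and 705 without its replicate 3. The share of higher genes was 68.4%, against 53.6% with DESeq2.

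The comparison of WT at 8 h with 0 h asked which transcripts change during a longer shade, without a white-light group at 8 h. HFR1 (AT1G02340), a bHLH gene that limits the shade response, rose from 1.37 ± 0.322 to 106 ± 14.8 CPM (6.26 ± 0.37, adjusted p = 2.45e-12). XTH15 (AT4G14130), which encodes a cell wall xyloglucan hydrolase or transferase, rose from 8.14 ± 2.0 to 173 ± 6.63 CPM (4.41 ± 0.38), and the photoreceptor gene PHYA (AT1G09570) from 68.0 ± 14.8 to 395 ± 32.0 CPM (2.54 ± 0.26). CYP96A5 (AT2G21910), a cytochrome P450 gene, had no counts in WT at 0 h and reached 19.6 CPM, at least 238-fold higher than a floor of 3 counts per library. The lowest folds included IPMI1 (AT3G58990, -2.51 ± 0.26), GSTF11 (AT3G03190, -2.48 ± 0.34) and FMOGS-OX3 (AT1G62560, -2.29 ± 0.31), which serve the synthesis of aliphatic glucosinolates, the sulfur-rich defence compounds of this plant. With edgeR, 4131 genes were called, 2598 higher and 1533 lower, of which 399 and 358 changed at least 2-fold.

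Shade markers, SAUR genes and early auxin response genes were also higher at 8 h. Shade markers were higher at 23 of 24 members (23 adjusted over the list alone; median 3.01; camera adjusted p = 9.42e-34; adjusted p = 3.51e-05 with an estimated correlation). SAUR genes were higher at 18 of 18 (18 adjusted over the list alone; camera adjusted p = 3.17e-29; adjusted p = 0.0073 with an estimated correlation). Early auxin response genes rose at 15 of 22 (15 adjusted over the list alone), with GH3.5 (AT4G27260), an auxin-conjugating enzyme gene, at 2.2 ± 0.19 (camera adjusted p = 2.16e-15, and adjusted p = 0.00904 with an estimated correlation). For auxin biosynthesis the median was -0.05 and the mean 0.80, so that they differ in sign, with 3 higher and 1 lower of 10 measured, 4 and 2 adjusted over the list alone (camera adjusted p = 0.303, and adjusted p = 0.588 with an estimated correlation). The light signalling list had 24 higher and 0 lower of 41 measured, 26 and 1 adjusted over the list alone, with BBX24 (AT1G06040) at 1.32 ± 0.13 and BBX29 (AT5G54470) at 2.36 ± 0.25 (camera adjusted p = 8.23e-13, and adjusted p = 0.00369 with an estimated correlation). Cell wall loosening genes had 9 higher and 3 lower of 24 measured, 10 and 4 adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.00689 with an estimated correlation), among them EXPA8 (AT2G40610), an expansin gene (1.93 ± 0.26). The gibberellin list had 8 higher and 2 lower of 15 measured, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000372, and adjusted p = 0.0061 with an estimated correlation), including the inactivating enzyme gene GA2OX1 (AT1G78440, 2.73 ± 0.37). PIF4 (1.33 ± 0.20) and PIF5 (1.29 ± 0.21) also rose.

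Several lists passed at 8 h in WT with the preset correlation and not with an estimated one. Photosynthesis genes had 9 higher and 2 lower of 40 measured, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0053, and adjusted p = 0.818 with an estimated correlation), with LHCB3 (AT5G54270), a light-harvesting protein gene, at 1.2 ± 0.29. The clock list had 8 higher and 1 lower of 23 measured, 8 and 2 adjusted over the list alone, with GI (AT1G22770) at 1.98 ± 0.22 and PRR7 (AT5G02810) at 1.65 ± 0.21 (camera adjusted p = 0.00817, and adjusted p = 0.257 with an estimated correlation). The dark and sugar starvation list had 8 higher and 0 lower of 22 measured, 8 and 0 adjusted over the list alone, with the senescence regulator gene ORE1 (AT5G39610) at 2.45 ± 0.28 (camera adjusted p = 0.0013, and adjusted p = 0.625 with an estimated correlation). Jasmonate genes had 1 higher and 5 lower of 20 measured, 1 and 6 adjusted over the list alone, with the synthesis gene LOX3 (AT1G17420) at -0.81 ± 0.16 (camera adjusted p = 0.00723, and adjusted p = 0.52 with an estimated correlation). Touch and wounding genes had 0 higher and 5 lower of 15 measured, 0 and 5 adjusted over the list alone, with ZAT12 (AT5G59820) at -2.33 ± 0.49 (camera adjusted p = 0.04, and adjusted p = 0.782 with an estimated correlation). Root tissue markers had a median of -1.17 with none of 23 called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.697 with an estimated correlation), beside the root marker score of -0.42 ± 1.64 in this group. In the cytokinin list, whose test did not pass (camera adjusted p = 0.0713; adjusted p = 0.379 with an estimated correlation), the response regulator genes ARR4 (AT1G10470, -1.19 ± 0.14) and ARR8 (AT2G41310, -1.05 ± 0.22) fell, with 3 higher and 5 lower of 16 measured, 3 and 6 adjusted over the list alone. The flavonoid list had 1 higher and 5 lower of 20 measured, 1 and 8 adjusted over the list alone and did not pass (camera adjusted p = 0.156, and adjusted p = 0.847 with an estimated correlation). The count of 4131 was 2211 without WT 0 h replicate 1, 2387 without its replicate 3 and 2096 without WT 8 h replicate 3.

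The direct comparison of 8 h with 1 h in WT asked which changes are early and which late. YUC9 fell from 42.7 ± 4.25 to 7.79 ± 0.0816 CPM (-2.45 ± 0.34, adjusted p = 1.94e-05) and HAT2 (AT5G47370), a homeodomain gene induced by auxin, from 200 ± 5.68 to 35.6 ± 2.22 CPM (-2.49 ± 0.17). XTH15 was higher at 8 h than at 1 h (3.74 ± 0.36), as were GI (2.63 ± 0.23) and BBX24 (1.72 ± 0.13). Early auxin response genes had 1 higher and 10 lower of 22 measured, 2 and 14 adjusted over the list alone (camera adjusted p = 3.64e-05, and adjusted p = 0.257 with an estimated correlation). SAUR genes had 0 higher and 8 lower of 18 measured, 0 and 10 adjusted over the list alone (camera adjusted p = 5.06e-05, and adjusted p = 0.503 with an estimated correlation). Light signalling genes had 20 higher and 1 lower of 41 measured, 25 and 2 adjusted over the list alone (camera adjusted p = 7.57e-16, and adjusted p = 0.00137 with an estimated correlation). Clock genes had 11 higher and 2 lower of 23 measured, 13 and 2 adjusted over the list alone (camera adjusted p = 3.13e-09, and adjusted p = 0.00308 with an estimated correlation). Cytokinin genes had 0 higher and 6 lower of 16 measured, 1 and 9 adjusted over the list alone (camera adjusted p = 2.86e-06, and adjusted p = 0.00369 with an estimated correlation). With edgeR, 1760 genes were called, 962 higher and 798 lower. The count was 986 in a fit of the compared groups alone. It was 1159 without WT 1 h replicate 2, 1054 without WT 8 h replicate 2 and 979 without its replicate 3.

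Of the 767 genes higher at 1 h in WT, 556 were also higher at 8 h, and of the 354 lower genes 189 were also lower. Independent lists of these sizes would share 92.4 and 25.2. Both lists use the same 0 h libraries, and in 20 simulations of unchanged WT groups such lists shared up to 422 and 145. Of the 767 genes, 164 were lower at 8 h than at 1 h, 56 higher, and 547 had no call between the times. In hy5, 276 of 780 higher genes and 235 of 679 lower genes at 1 h had the same call at 8 h, against 35.3 and 32.2 for independent lists and up to 246 and 190 in 20 such simulations of hy5.

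**Figure D3:**
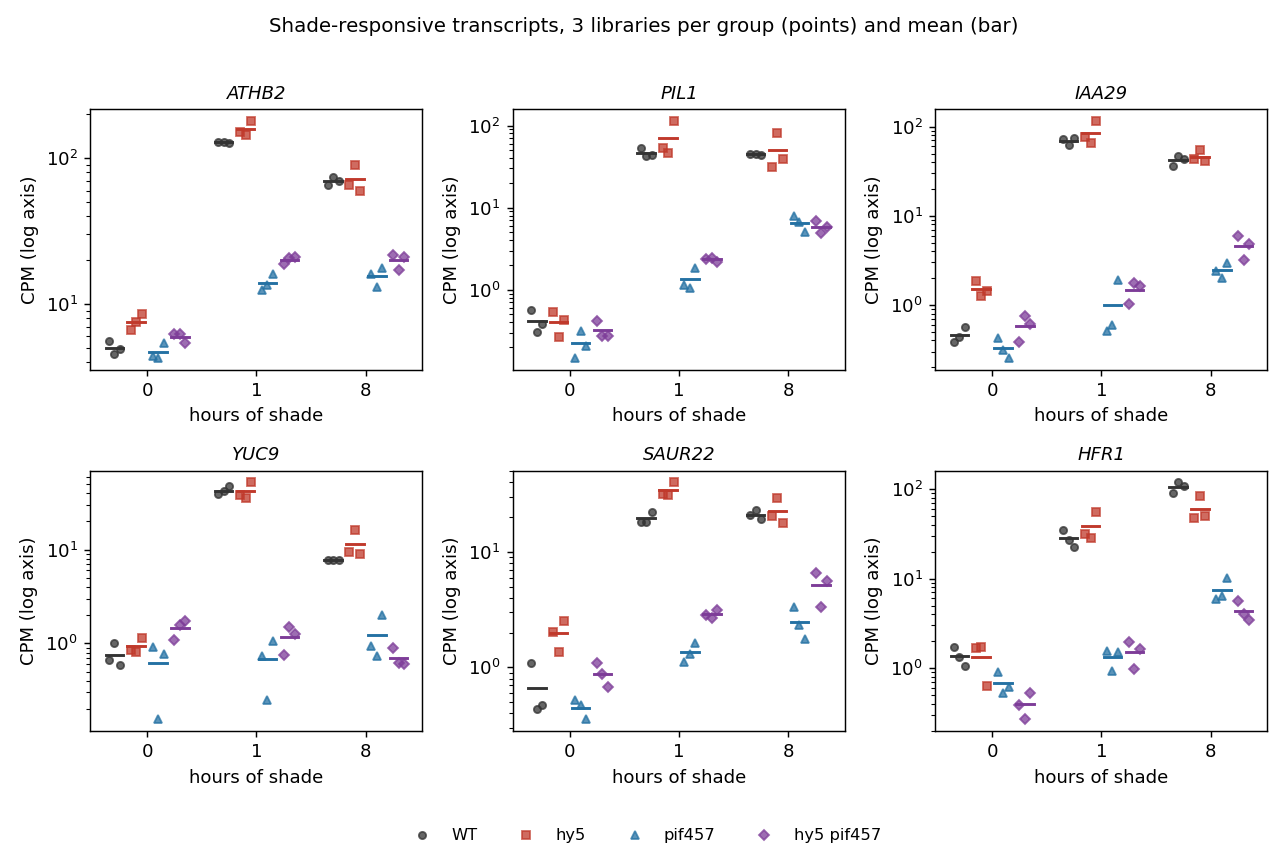
Levels of ATHB2, PIL1, IAA29, YUC9, SAUR22 and HFR1 in CPM (log axis) against hours of simulated shade for the 4 genotypes, with each point 1 library and each bar the mean of 3. ATHB2 reaches 129 ± 1.04 CPM in WT and 158 ± 18.3 CPM in hy5 at 1 h, but 14.1 ± 1.84 CPM in pif457 and 20.1 ± 1.1 CPM in hy5 pif457.

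Before shade, hy5 was compared with WT to show what loss of HY5 changes in white light. CHS (AT5G13930), which encodes chalcone synthase of the flavonoid pathway, stood at 438 ± 173 CPM in WT and 81.7 ± 45.9 CPM in hy5 (-2.42 ± 0.42, adjusted p = 0.000603). FLS1 (AT5G08640), a flavonol synthase gene, stood at 73.5 ± 17.0 and 13.3 ± 7.14 CPM (-2.46 ± 0.36). Of the flavonoid list, 17 of 20 members were lower and 1 higher (19 lower and 1 higher adjusted over the list alone; median -3.16; camera adjusted p = 2.46e-15; adjusted p = 0.0909 with an estimated correlation). The higher member was MYBL2 (AT1G71030, 1.92 ± 0.34), a repressor of anthocyanin synthesis. SAUR genes were higher at 17 of 18 members (18 adjusted over the list alone; median 1.33; camera adjusted p = 1.52e-18; adjusted p = 0.0426 with an estimated correlation), with SAUR61 (AT1G29420) at 2.11 ± 0.37. PKS4 (AT5G04190), a phytochrome kinase substrate gene, was higher (2.19 ± 0.25), and ELIP1 (AT3G22840), a light stress gene (-4.33 ± 0.53), and GA3OX1 (AT1G15550), a gibberellin synthesis gene (-1.36 ± 0.26), were lower. The lowest fold was that of MRD1 (AT1G53480), at 32.9 ± 3.21 CPM in WT and 0.115 ± 0.118 CPM in hy5 (-8.06 ± 0.46), but it stood at 13.7 ± 1.78 CPM in hy5 pif457.

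The remaining groups at 0 h in hy5 were mixed. The salicylate and immunity list was higher with 10 of 17 members (15 adjusted over the list alone; median 1.58; camera adjusted p = 3.71e-06; adjusted p = 0.402 with an estimated correlation). Without hy5 0 h replicate 3 its median was 0.36 and 2 of 17 members were called. ICS1 (AT1G74710), the main salicylate synthesis gene, was higher (1.16 ± 0.17). Clock genes had 9 higher and 6 lower of 23 measured, 12 and 8 adjusted over the list alone, with LNK1 (AT5G64170) at 1.73 ± 0.18 and ELF4 (AT2G40080) at -1.46 ± 0.24 (camera adjusted p = 0.13, and adjusted p = 0.602 with an estimated correlation). The photosynthesis list had 9 higher and 2 lower of 40 measured, 11 and 2 adjusted over the list alone (camera adjusted p = 0.000918, and adjusted p = 0.791 with an estimated correlation). Shade markers had 7 higher and 0 lower of 24 measured, 9 and 0 adjusted over the list alone (camera adjusted p = 8.77e-05, and adjusted p = 0.188 with an estimated correlation). Early auxin response genes had 8 higher and 0 lower of 22 measured, 11 and 0 adjusted over the list alone (camera adjusted p = 1.26e-05, and adjusted p = 0.208 with an estimated correlation). Carotenoid genes had 2 higher and 2 lower of 15 measured, 2 and 2 adjusted over the list alone (camera adjusted p = 0.535, and adjusted p = 0.917 with an estimated correlation), with ZEP (AT5G67030), a xanthophyll epoxidase gene, at 0.95 ± 0.20. With edgeR, 2047 genes were called, 1370 higher and 677 lower. The count was 261 in a fit of the compared groups alone and 1353 without the 12 libraries rich in rRNA. It was 722 without WT 0 h replicate 1, 3129 without its replicate 2, 676 without its replicate 3 and 1079 without hy5 0 h replicate 1. The share of higher genes was 66.9%, and 55.2% without rRNA and organelle genes.

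The same comparison for pif457 at 0 h asked whether this mutant differs before shade, and edgeR called 18 genes, 4 higher and 14 lower. PIF5 (-4.26 ± 0.25) and PIF7 (-3.38 ± 0.25) were lower. MRD1 was at 0.0503 ± 0.0436 CPM (-9.25 ± 0.52), PAO3 (AT3G59050), a polyamine oxidase gene, was lower (-0.51 ± 0.08), and ARP9 (AT5G43500), an actin-related protein gene, was higher (1.41 ± 0.09). The flavonoid list had no member called by edgeR (0 adjusted over the list alone), with a median of -1.15 (camera adjusted p = 9.2e-07; adjusted p = 0.403 with an estimated correlation). The abscisic acid and cold list had none called and 1 lower adjusted over the list alone, with a median of -0.73 (camera adjusted p = 2.08e-05; adjusted p = 0.411 with an estimated correlation). At unadjusted p under 0.05 there were 1383 genes, near the 1078 that chance gives, and the count was 8 in a fit of the compared groups alone, 38 with DESeq2 and 153 without WT 0 h replicate 2.

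For hy5 pif457 at 0 h the flavonoid pathway was again lower: CHS stood at 82.4 ± 11.9 CPM (-2.41 ± 0.42) and FLS1 at 11.2 ± 1.55 CPM (-2.72 ± 0.37). Of the list, 14 of 20 members were lower and 1 higher (19 lower and 1 higher adjusted over the list alone; median -2.76; camera adjusted p = 4.81e-12; adjusted p = 0.159 with an estimated correlation). MRD1 was at 13.7 ± 1.78 CPM. The dark and sugar starvation list was higher with 15 of 22 members (17 higher and 1 lower adjusted over the list alone), such as TPS11 (AT2G18700), a trehalose phosphate synthase-like gene, at 1.51 ± 0.25 and ORE1 at 1.41 ± 0.28 (camera adjusted p = 3.53e-10, and adjusted p = 0.208 with an estimated correlation). SAUR genes had 7 higher and 0 lower of 18 measured, 13 and 0 adjusted over the list alone (camera adjusted p = 7.1e-07, and adjusted p = 0.372 with an estimated correlation). Clock genes had 9 higher and 4 lower of 23 measured, 11 and 6 adjusted over the list alone, with RVE1 (AT5G17300) at 1.06 ± 0.17 (camera adjusted p = 0.0234, and adjusted p = 0.374 with an estimated correlation). Root tissue markers had a median of 1.21 with 1 of 23 higher (1 adjusted over the list alone; camera adjusted p = 0.00414; adjusted p = 0.737 with an estimated correlation). These libraries had a root marker score of 2.35 ± 0.326 against 1.06 ± 0.323 in WT, and the high rRNA share. With edgeR, 1927 genes were called, 1265 higher and 662 lower. The count was 752 without WT 0 h replicate 1, 580 without its replicate 3, 973 without hy5 pif457 0 h replicate 2 and 523 without its replicate 3. The share of higher genes was 65.6%, and 53.3% without rRNA and organelle genes.

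The responses of hy5 asked whether shade still acts without HY5. At 1 h ATHB2 rose to 158 ± 18.3 CPM (4.38 ± 0.15), PIL1 to 70.6 ± 36.8 CPM (7.4 ± 0.40) and IAA29 to 85.5 ± 26.3 CPM (5.8 ± 0.33). All 24 shade markers were higher (24 adjusted over the list alone; camera adjusted p = 2.51e-56; adjusted p = 8.75e-07 with an estimated correlation). So were all 18 SAUR genes (18 adjusted over the list alone; camera adjusted p = 2.29e-38; adjusted p = 0.00256 with an estimated correlation). PIF4 (-1.08 ± 0.20), PIF5 (-0.91 ± 0.20) and PIF7 (-1.74 ± 0.22) fell. Cell cycle and DNA replication genes had a median of -0.34 with none of 22 called by edgeR (0 adjusted over the list alone; camera adjusted p = 1.76e-06; adjusted p = 0.52 with an estimated correlation). With edgeR, 1459 genes were called, 780 higher and 679 lower, beside root marker scores of 1.09 ± 0.418 at 0 h and 2.5 ± 0.264 at 1 h. The count was 2324 in a fit of the compared groups alone with the replicate number as a block and 898 without hy5 1 h replicate 1.

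At 8 h in hy5, PIL1 (6.91 ± 0.40), HFR1 (5.49 ± 0.36) and XTH15 (4.44 ± 0.38) were higher, and the glucosinolate genes MYB29 (AT5G07690, -2.23 ± 0.38) and CYP79F1 (AT1G16410, -2.33 ± 0.43) were lower. Shade markers had 19 higher and 0 lower of 24 measured, 20 and 1 adjusted over the list alone (camera adjusted p = 8.85e-34, and adjusted p = 3.51e-05 with an estimated correlation). SAUR genes had 10 higher and 0 lower of 18 measured, 14 and 0 adjusted over the list alone (camera adjusted p = 2.16e-15, and adjusted p = 0.075 with an estimated correlation). Cell wall loosening genes had 7 higher and 1 lower of 24 measured, 9 and 3 adjusted over the list alone (camera adjusted p = 0.000344, and adjusted p = 0.00369 with an estimated correlation). The abscisic acid and cold list had 6 higher and 0 lower of 20 measured, 7 and 0 adjusted over the list alone, with RD29A (AT5G52310) at 2.77 ± 0.44 and COR15B (AT2G42530) at 3.51 ± 0.74 (camera adjusted p = 0.000372, and adjusted p = 0.52 with an estimated correlation). Chlorophyll synthesis genes had 0 higher and 6 lower of 17 measured, 0 and 8 adjusted over the list alone, with HEMA1 (AT1G58290), which encodes an early enzyme of the pathway, at -1.12 ± 0.21 (camera adjusted p = 7.81e-07, and adjusted p = 0.469 with an estimated correlation). Stomatal lineage markers had 1 higher and 3 lower of 15 measured, 1 and 4 adjusted over the list alone, with POLAR (AT4G31805) at -1.25 ± 0.21 (camera adjusted p = 0.00514, and adjusted p = 0.608 with an estimated correlation). With edgeR, 1999 genes were called, 975 higher and 1024 lower (48.8% higher, and 57.6% without rRNA and organelle genes), beside root marker scores of 1.09 ± 0.418 at 0 h and 1.8 ± 0.078 at 8 h. The count was 497 in a fit of the compared groups alone, and no left-out library moved it by more than 1.5 times.

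The difference between the hy5 and WT responses was tested directly. At 1 h edgeR called 0 genes, with 2409 at unadjusted p under 0.05 (chance gives 1078) and 38 called by DESeq2. SAUR genes rose less in hy5 at 1 h by the list test, with a median difference of -0.83 and 0 members called (9 lower adjusted over the list alone; camera adjusted p = 6.29e-11; adjusted p = 0.165 with an estimated correlation). At 8 h PKS4 (-2.53 ± 0.33), ELIP2 (AT4G14690), a light stress gene (-3.65 ± 0.65), BBX24 (-1.25 ± 0.18), LNK1 (-1.82 ± 0.25) and PIF5 (-1.58 ± 0.29) had more negative responses in hy5 than in WT. ELF4 (1.75 ± 0.34) and JMJ30 (AT3G20810), a clock-linked histone demethylase gene (2.28 ± 0.41), had more positive ones. PKS4, LNK1, PIF5 and the SAUR list were already higher in hy5 than in WT at 0 h, and ELF4 lower. Their response differences therefore start from unequal levels. PIF5 was at 254.2% of WT in hy5 at 0 h and at 85.2% at 8 h (edgeR adjusted p = 0.55 at 8 h). Light signalling genes had 1 higher and 5 lower of 41 measured, 2 and 16 adjusted over the list alone (camera adjusted p = 1.44e-07, and adjusted p = 0.0329 with an estimated correlation). SAUR genes had 0 higher and 7 lower of 18 measured, 0 and 16 adjusted over the list alone (camera adjusted p = 2.46e-15, and adjusted p = 0.0752 with an estimated correlation). In all 329 genes were called at 8 h, 95 with a more positive and 234 with a more negative response. The count was 23 in a fit of the compared groups alone, 131 with the root marker score as a covariate, 624 with DESeq2, 197 without a filter on low counts, 215 without rRNA and organelle genes and 123 without the 12 libraries rich in rRNA. It was 162 without WT 0 h replicate 1, 112 without its replicate 3, 210 without WT 8 h replicate 1, 117 without its replicate 2, 85 without its replicate 3, 128 without hy5 0 h replicate 1, 147 without its replicate 2, 586 without its replicate 3, 80 without hy5 8 h replicate 1 and 644 without its replicate 2. The share of more positive responses was 28.9%, and 49.3% without rRNA and organelle genes. Leaving out 1 library changed the count of 0 at 1 h to 1 without WT 0 h replicate 2 and 1 without hy5 1 h replicate 3.

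The responses of pif457 asked how much of the shade response remains in this mutant, where the PIF4 transcript was not lost. At 1 h ATHB2 rose from 4.72 ± 0.631 to 14.1 ± 1.84 CPM (1.58 ± 0.14, adjusted p = 3.91e-07), and BIC2 (-1.33 ± 0.18) and BBX24 (-0.9 ± 0.13) fell. The shade marker list had 2 higher and 0 lower of 24 measured, 3 and 1 adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.000331, and adjusted p = 0.257 with an estimated correlation). Clock genes were lower as a list, with a median of -0.41 and 4 of 23 members called (10 adjusted over the list alone; camera adjusted p = 8.86e-14; adjusted p = 0.000297 with an estimated correlation). With edgeR, 49 genes were called, 6 higher and 43 lower. The count was 0 in a fit of the compared groups alone (1533 at unadjusted p under 0.05 with all groups), 25 in that fit with the replicate number as a block, 114 with DESeq2, 28 without a filter on low counts and 16 without the 12 libraries rich in rRNA. It was 10 without pif457 0 h replicate 1, 14 without its replicate 2, 23 without its replicate 3, 14 without pif457 1 h replicate 1, 13 without its replicate 2 and 6 without its replicate 3.

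At 8 h in pif457, PIL1 reached 6.58 ± 1.44 CPM (4.87 ± 0.44), HFR1 7.51 ± 2.33 CPM (3.45 ± 0.38) and ATHB2 15.6 ± 2.28 CPM (1.73 ± 0.14). PIF3 (AT1G09530), a bHLH gene of the same family, rose (1.4 ± 0.14), and FKF1 (AT1G68050), a blue light receptor gene of the clock, fell (-1.13 ± 0.27). Shade markers had 11 higher and 0 lower of 24 measured, 17 and 0 adjusted over the list alone (camera adjusted p = 1.29e-10, and adjusted p = 0.0167 with an estimated correlation). Early auxin response genes had 4 higher and 1 lower of 22 measured, 11 and 1 adjusted over the list alone (camera adjusted p = 0.000311, and adjusted p = 0.363 with an estimated correlation). SAUR genes had 5 higher and 0 lower of 18 measured, 6 and 0 adjusted over the list alone (camera adjusted p = 0.00524, and adjusted p = 0.674 with an estimated correlation). Root tissue markers had 2 higher and 0 lower of 23 measured, 11 and 0 adjusted over the list alone (camera adjusted p = 0.000497, and adjusted p = 0.68 with an estimated correlation), beside a root marker score of 1.87 ± 1.75 against 0.438 ± 1.45 at 0 h. The libraries at 8 h are among the 12 with the high rRNA share. With edgeR, 2143 genes were called, 1156 higher and 987 lower (53.9% higher, and 44% without rRNA and organelle genes). The count was 13 in a fit of the compared groups alone and 665 with the root marker score as a covariate. It was 548 without pif457 0 h replicate 2, 1346 without its replicate 3, 4235 without pif457 8 h replicate 1 and 484 without its replicate 3.

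Tested against WT, the pif457 response at 1 h was smaller in several lists. YUC9 differed by -5.6 ± 0.62 (adjusted p = 1.26e-06), IAA29 by -5.58 ± 0.67, HAT2 by -3.66 ± 0.25 and ATHB2 by -3.11 ± 0.20. Shade markers had 17 of 24 with a smaller response (23 adjusted over the list alone; median -2.98; camera adjusted p = 3.55e-91; adjusted p = 2.94e-08 with an estimated correlation). In the SAUR genes, 17 of 18 responded less (18 adjusted over the list alone; camera adjusted p = 6.81e-92; adjusted p = 1.29e-05 with an estimated correlation). In the early auxin response genes, 13 of 22 responded less (18 adjusted over the list alone; camera adjusted p = 2.31e-60; adjusted p = 3.43e-06 with an estimated correlation). The auxin biosynthesis list had 0 higher and 4 lower of 10 measured, 1 and 4 adjusted over the list alone (camera adjusted p = 0.00306, and adjusted p = 0.0235 with an estimated correlation). The gibberellin list had 0 higher and 4 lower of 15 measured, 0 and 4 adjusted over the list alone (camera adjusted p = 9.15e-07, and adjusted p = 0.000317 with an estimated correlation), with GA20OX1 at -3.29 ± 0.57. With edgeR, 188 genes were called, 6 with a more positive and 182 with a more negative response, and no left-out library moved this count by more than 1.5 times.

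At 8 h the pif457 response differed from that of WT by -3.64 ± 0.64 for IAA29, -3.28 ± 0.49 for XTH15, -2.07 ± 0.20 for ATHB2 and -1.83 ± 0.35 for PHYA. Shade markers had 14 of 24 with a smaller response (19 adjusted over the list alone; camera adjusted p = 4e-27; adjusted p = 0.000147 with an estimated correlation). In the SAUR genes, 14 of 18 responded less (17 adjusted over the list alone; camera adjusted p = 6.75e-31; adjusted p = 0.00596 with an estimated correlation). In the early auxin response genes, 9 of 22 responded less (10 adjusted over the list alone; camera adjusted p = 3.58e-11; adjusted p = 0.0329 with an estimated correlation). The cell wall list had 1 higher and 6 lower of 24 measured, 1 and 7 adjusted over the list alone (camera adjusted p = 0.00402, and adjusted p = 0.019 with an estimated correlation). The light signalling list had 0 higher and 5 lower of 41 measured, 0 and 7 adjusted over the list alone (camera adjusted p = 1.73e-07, and adjusted p = 0.0339 with an estimated correlation). The flavonoid list had 3 higher and 1 lower of 20 measured, 12 and 1 adjusted over the list alone and a median of 1.96 (camera adjusted p = 0.000299, and adjusted p = 0.58 with an estimated correlation). Root tissue markers had a median of 2.91 with 0 called by edgeR (20 higher adjusted over the list alone; camera adjusted p = 1.13e-10; adjusted p = 0.363 with an estimated correlation). In all 629 genes were called, 280 more positive and 349 more negative. Of the groups in this contrast only pif457 at 8 h is rRNA-rich, so a batch cannot be told apart from the response. The count was 124 in a fit of the compared groups alone, 160 with the root marker score as a covariate and 1150 with DESeq2. It was 269 without WT 0 h replicate 1, 299 without its replicate 3, 1114 without WT 8 h replicate 1, 261 without its replicate 2, 286 without its replicate 3, 357 without pif457 0 h replicate 1, 312 without its replicate 2, 2289 without pif457 8 h replicate 1 and 320 without its replicate 3. The share of more positive responses was 44.5%, and 56.2% with DESeq2.

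The responses of hy5 pif457 asked what remains when the mutations are combined. At 1 h ATHB2 rose to 20.1 ± 1.1 CPM (1.76 ± 0.14), and LEA2 (AT1G02820, -1.94 ± 0.29) and ERF2 (AT5G47220), an ethylene response factor gene (-1.3 ± 0.21), fell. Shade markers had 2 higher and 0 lower of 24 measured, 4 and 0 adjusted over the list alone (camera adjusted p = 2.43e-06, and adjusted p = 0.0922 with an estimated correlation). Touch and wounding genes had a median of -0.60 with 0 called by edgeR (5 lower adjusted over the list alone; camera adjusted p = 2.19e-07; adjusted p = 0.355 with an estimated correlation). With edgeR, 39 genes were called, 12 higher and 27 lower. The count was 270 in a fit of the compared groups alone and 92 with DESeq2. It was 18 without hy5 pif457 0 h replicate 1, 21 without its replicate 2, 16 without its replicate 3, 20 without hy5 pif457 1 h replicate 1, 15 without its replicate 2 and 13 without its replicate 3.

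At 8 h in hy5 pif457, PIL1 (4.17 ± 0.44) and HFR1 (3.45 ± 0.44) rose, and BHLH39 (AT3G56980), a regulator gene of iron uptake, fell from 25.5 ± 10.2 to 2.67 ± 1.6 CPM (-3.26 ± 0.63). The clock gene LHY (AT1G01060) fell from 171 ± 11.3 to 27.5 ± 1.09 CPM (-2.64 ± 0.46) and ELIP2 from 13.7 ± 4.12 to 1.62 ± 0.521 CPM (-3.07 ± 0.49). The iron list had 14 of 19 lower (16 adjusted over the list alone; median -1.8; camera adjusted p = 3.92e-08; adjusted p = 0.0922 with an estimated correlation). Shade markers had 7 higher and 1 lower of 24 measured, 7 and 1 adjusted over the list alone (camera adjusted p = 0.000117, and adjusted p = 0.201 with an estimated correlation). Carotenoid genes had 0 higher and 4 lower of 15 measured, 0 and 6 adjusted over the list alone (camera adjusted p = 0.0056, and adjusted p = 0.658 with an estimated correlation). Root tissue markers had a median of -1.48 with 0 called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.697 with an estimated correlation), beside root marker scores of 2.35 ± 0.326 at 0 h and 0.779 ± 0.275 at 8 h. With edgeR, 2355 genes were called, 1019 higher and 1336 lower. The count was 6634 in a fit of the compared groups alone and 985 with the root marker score as a covariate. It was 1569 without hy5 pif457 0 h replicate 1, 1190 without its replicate 2, 860 without its replicate 3, 723 without hy5 pif457 8 h replicate 1 and 823 without its replicate 3. The share of higher genes was 43.3%, against 55.0% with RLE size factors and 57.4% without rRNA and organelle genes.

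Tested against WT, the hy5 pif457 response at 1 h was smaller for YUC9 (-6.14 ± 0.58), IAA29 (-5.91 ± 0.62), HAT2 (-4.13 ± 0.25) and PHYB (-1.39 ± 0.20). Shade markers had 15 of 24 with a smaller response (22 adjusted over the list alone; camera adjusted p = 2.92e-58; adjusted p = 8.75e-07 with an estimated correlation). In the SAUR genes, 17 of 18 responded less (18 adjusted over the list alone; camera adjusted p = 1.62e-57; adjusted p = 0.000265 with an estimated correlation). In the early auxin response genes, 16 of 22 responded less (20 adjusted over the list alone; camera adjusted p = 3.07e-50; adjusted p = 1.29e-05 with an estimated correlation). With edgeR, 209 genes were called, 21 more positive and 188 more negative, and no left-out library moved this count by more than 1.5 times.

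At 8 h the hy5 pif457 response was smaller than that of WT for XTH15 (-4.18 ± 0.49), YUC8 (-4.25 ± 0.53), PHYA (-2.28 ± 0.35) and BBX24 (-1.44 ± 0.18). SAUR genes had 18 of 18 with a smaller response (18 adjusted over the list alone; camera adjusted p = 3.23e-20; adjusted p = 0.0327 with an estimated correlation). In the shade markers, 20 of 24 responded less (20 adjusted over the list alone; camera adjusted p = 2.75e-20; adjusted p = 0.000807 with an estimated correlation). In the light signalling genes, 20 of 41 responded less (24 adjusted over the list alone; camera adjusted p = 9.78e-12; adjusted p = 0.00548 with an estimated correlation). Cell wall genes had 0 higher and 10 lower of 24 measured, 1 and 13 adjusted over the list alone (camera adjusted p = 0.000336, and adjusted p = 0.00369 with an estimated correlation). With edgeR, 2950 genes were called, 1022 more positive and 1928 more negative. The count was 4492 in a fit of the compared groups alone. It was 1508 without WT 0 h replicate 1, 1543 without its replicate 3, 1122 without WT 8 h replicate 3, 1940 without hy5 pif457 0 h replicate 1, 1689 without its replicate 2, 1520 without its replicate 3, 1276 without hy5 pif457 8 h replicate 1 and 1283 without its replicate 3. The share of more positive responses was 34.6%, against 48.0% with RLE size factors, 48.0% with DESeq2 and 55.5% without rRNA and organelle genes.

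The difference between the hy5 pif457 and pif457 responses asked what the hy5 mutation adds in the pif457 background. At 8 h, of the groups in it only pif457 at 0 h lies outside the rRNA-rich libraries. A batch therefore cannot be told apart from an effect of hy5 there. At 1 h edgeR called 0 genes, with 434 at unadjusted p under 0.05 and 0 called by DESeq2. Chance gives 1078, so this test was conservative and its 0 calls do not show equal responses. At 8 h PKS4 (-1.53 ± 0.34), ELIP2 (-3.66 ± 0.64), ZEP (-1.59 ± 0.29) and LNK1 (-1.53 ± 0.25) had more negative responses in hy5 pif457, and FKF1 (2.13 ± 0.38) and LUX (AT3G46640), a clock gene (1.26 ± 0.21), more positive ones. The cell wall genes XTH19 (AT4G30290, -4.56 ± 0.81) and XTH18 (AT4G30280, -3.58 ± 0.75), both typical of roots, were also more negative, and lost their calls with the root marker score as a covariate. Root tissue markers had 0 higher and 14 lower of 23 measured, 0 and 20 adjusted over the list alone and a median of -2.7 (camera adjusted p = 1.96e-05, and adjusted p = 0.588 with an estimated correlation). With edgeR, 4690 genes were called, 1658 more positive and 3032 more negative. The count was 462 with the root marker score as a covariate and 1954 in a fit of the compared groups alone. It was 2353 without pif457 0 h replicate 2, 2096 without pif457 8 h replicate 3, 2657 without hy5 pif457 0 h replicate 3, 2787 without hy5 pif457 8 h replicate 1 and 2865 without its replicate 3. The share of more positive responses was 35.4%, and 47.8% without rRNA and organelle genes.

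The last question was whether the mutations add up, that is, whether the hy5 pif457 response departs from the sum of the hy5 and pif457 effects on the log2 scale. At 1 h edgeR called 0 genes, with 540 at unadjusted p under 0.05 and 0 called by DESeq2. Chance gives 1078, so this test too was conservative and its 0 calls do not show additivity. SAUR genes departed as a list at 1 h, with a median of 0.96 and 0 called (6 higher adjusted over the list alone; camera adjusted p = 1.05e-14; adjusted p = 0.0864 with an estimated correlation). At 8 h 1297 genes were called, 165 positive and 1132 negative, led by root tissue markers with 0 higher and 15 lower of 23 measured, 0 and 22 adjusted over the list alone and a median of -4.45 (camera adjusted p = 1.17e-11, and adjusted p = 0.323 with an estimated correlation). None of the genes named for this comparison kept its call with every single library left out, so no single gene is given. The pif457 response within it runs from libraries with a low rRNA share to rRNA-rich ones, so a batch is not excluded. The count was 4 with the root marker score as a covariate, 11 in a fit of the groups concerned alone and 2127 with DESeq2. It was 6 without WT 0 h replicate 1, 2022 without WT 8 h replicate 1, 5 without its replicate 2, 673 without its replicate 3, 814 without hy5 0 h replicate 1, 16 without its replicate 2, 2568 without its replicate 3, 730 without hy5 8 h replicate 2, 2076 without pif457 0 h replicate 1, 272 without its replicate 2, 3325 without pif457 8 h replicate 1, 27 without its replicate 3, 762 without hy5 pif457 0 h replicate 2, 5 without its replicate 3, 23 without hy5 pif457 8 h replicate 1 and 293 without its replicate 3.

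Read across genotypes, the genes higher in WT at 1 h (767, median 0.61) had medians of 0.49 in hy5, 0.15 in pif457 and 0.09 in hy5 pif457, and 373, 5 and 8 of them were called there, against 27.7, 0.2 and 0.4 for independent lists. The genes lower at 1 h (354, median -0.60) had medians of -0.46, -0.29 and -0.16, with 163, 25 and 22 called. The genes higher in WT at 8 h (2598, median 0.44) had medians of 0.17, 0.20 and 0.00, and 598, 500 and 234 were called, against 117.5, 139.3 and 122.8 for independent lists. Those lower at 8 h (1533, median -0.57) had medians of -0.27, -0.26 and -0.06. Choosing genes in WT inflates the WT medians: chosen instead in hy5 at 1 h, the 780 higher genes had medians of 1.01 in hy5 and 0.70 in WT. The higher genes chosen at 8 h in hy5, pif457 and hy5 pif457 had medians of 0.65, 0.69 and 0.49 there and 0.51, 0.27 and 0.08 in WT.

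**Figure D4:**
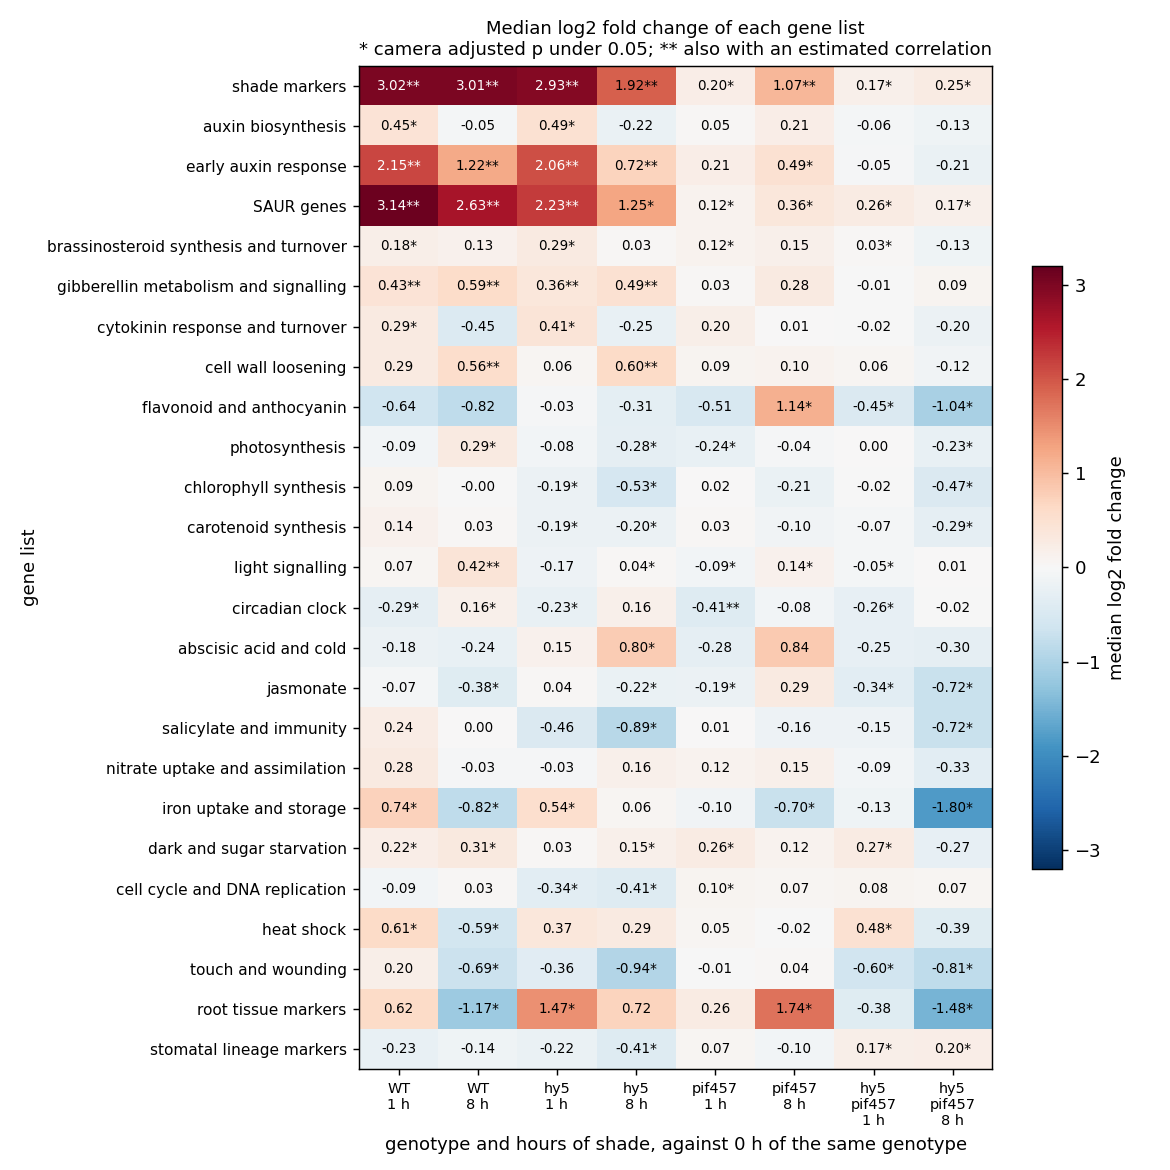
Heat map of the median log2 fold change of each of the 25 gene lists in the 8 shade responses against 0 h, with 1 asterisk for camera adjusted p under 0.05 and a pair of asterisks where this also holds with an estimated correlation. The shade marker median is 3.02 in WT and 2.93 in hy5 at 1 h, 0.20 in pif457 and 0.17 in hy5 pif457.

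**Figure D5:**
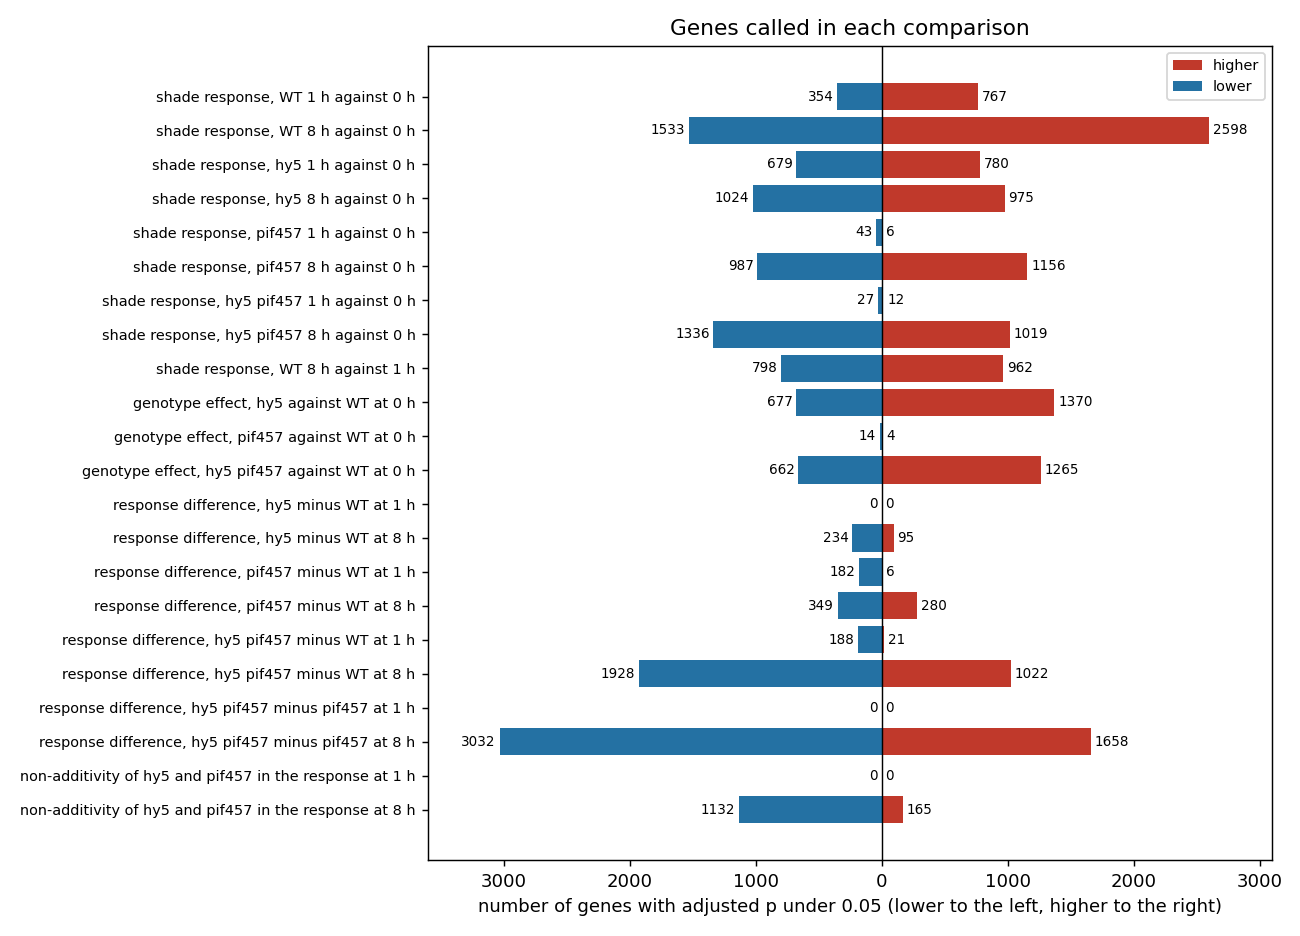
Number of genes called by edgeR (adjusted p under 0.05) as higher or lower in each of the 22 comparisons, with bars from 0. The counts run from 0 for the hy5 response difference at 1 h to 4690 for hy5 pif457 minus pif457 at 8 h.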

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

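The tests of scaling, root tissue share and the single hy5 library were chosen after their results were seen. So were the division of splits by mixing in shade, the runs without rRNA-rich libraries or rRNA and organelle genes, and the root marker covariate.

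Differences between genotypes under the same shade drew attention to 7 results, because the test of the difference itself called genes. The hy5 response at 8 h differed from that of WT at 329 genes. A fit of these groups alone called 23, and 3 of 100 splits of the libraries gave as many (highest other 274). The pif457 response at 1 h differed from WT at 188 genes, with ATHB2 at -3.11 ± 0.20, and 11 of 100 splits gave as many as the 157 of its own fit (highest other 1109). The share is a poor measure of chance here, since 9 of the 10 others keep the genotypes whole in shade and so their difference there, while of 84 splits that mix them 1 gave as many, the one with 1109. The pif457 response at 8 h differed at 629 genes, and 7 of 100 splits gave as many as 124 (highest other 496), where all 6 others keep the genotypes whole in shade and of 89 that mix them 0 gave as many. The hy5 pif457 response differed from WT at 209 genes at 1 h, where 3 of 100 splits gave as many as 245 (highest other 666), and at 2950 genes at 8 h, where 2 of 100 gave as many as 4492 (highest other 4637). It differed from the pif457 response at 8 h at 4690 genes, where 2 of 100 splits gave as many as 1954 (highest other 2409). The departure from additivity at 8 h covered 1297 genes, and 3 of 100 splits gave as many as 11 (highest other 3736). Of the splits that mix the genotypes in shade, 2 of 89 gave as many for hy5 at 8 h (highest 274), 1 of 88 and 0 of 86 for hy5 pif457 against WT at 1 and 8 h, and 0 of 92 for hy5 pif457 minus pif457 at 8 h. Shares under 0.05 refer to the counts of these smaller fits and were not adjusted over the comparisons. The splits mix libraries of genotypes that differ, which adds to the spread within groups, so a low share does not exclude chance. Mixed splits with counts far above the real one (274, 359 and 1109) point to a structure of the samples. The splits behind 666, 1116, 2409 and 4637 keep the genotypes whole in shade and so their difference there. Where the real count was 0, at 1 h for hy5 minus WT, hy5 pif457 minus pif457 and the departure from additivity, all 100 splits gave as many, with highest counts of 359, 1116 and 1528 and edgeR counts at unadjusted p under 0.05 of 2409, 434 and 540.

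For the 12 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In WT, 2 of 10 splits gave as many genes as the real 329 at 1 h (highest other 412), and 1 of 10 as many as 3135 at 8 h (highest other 0) and 986 for 8 h against 1 h (highest other 8). In hy5 the real counts were 1416 at 1 h and 497 at 8 h. In pif457 they were 0 at 1 h, where all 10 splits gave as many (highest other 6), and 13 at 8 h, and in hy5 pif457 270 at 1 h and 6634 at 8 h (highest other 1). The highest other count was 0 where not given. Against WT at 0 h they were 261 for hy5 and 2130 for hy5 pif457. For pif457 it was 8, where 2 of 10 gave as many (highest other 20).

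The rRNA share, a signal outside the comparisons, had a median of 9.28% in the 3 libraries of pif457 at 8 h and the 9 of hy5 pif457, against 0.72% in the others, and 5 comparisons set these libraries against the rest. A shift of scaling by these reads is argued against as the cause of most calls, since leaving out rRNA and organelle genes kept between 82% and 95.4% of the called genes in the 5 comparisons. It stays open for the balance of directions, which moved by over 10 percentage points in 2 of the 5 (65.6% to 53.3% higher for hy5 pif457 at 0 h). The balance also moved by over 10 points in comparisons without these libraries, hy5 against WT at 0 h and hy5 minus WT at 8 h. Such moves are therefore not particular to the rRNA-rich libraries. A library batch stays open: if it were the cause, the difference of hy5 pif457 from hy5 at 0 h should correlate by at least 0.3 with that of pif457 from WT at 8 h across 11630 genes. The correlation was 0.05 with the root marker score as a covariate (-0.04 to 0.25 with 1 library left out) but 0.61 without it, and the bound that would have excluded the batch, 0.1, lies inside that range. For the genotype contrasts with these libraries and the pif457 response at 8 h, a batch cannot be told apart from genotype or time, since no group has libraries on both sides, whereas the responses within hy5 pif457 lie on 1 side; an effect of the genotypes themselves remains untested.

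The root marker score differed between replicates, with 44.3% of its variance within groups, and 22 of 23 markers followed the mean of the others there (median r 0.83). Different shares of root tissue among the seedlings may explain it: within groups the photosynthesis score fell as the root score rose (Pearson r -0.41, permutation p = 0.023, adjusted 0.046 over 2 relations; Spearman rho -0.47, permutation p = 0.0091; 100000 permutations). The relation was weaker without the 2 farthest libraries (r -0.36) and ran from -0.52 to -0.29 with 1 library left out, so it rests in part on single libraries. Library depth is argued against as the cause (r 0.26, permutation p = 0.21, adjusted 0.21; rho 0.34, p = 0.11; r 0.25 without the 2 farthest, 0.12 to 0.38 with 1 left out). With the score as a covariate the 8 h counts were 462 for hy5 pif457 minus pif457 and 4 for the departure from additivity, but 3680 for hy5 pif457 minus WT, so only some of the large contrasts fell with it.

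The salicylate and immunity list was higher in hy5 than in WT at 0 h with a median of 1.58, which stays 1.58 with ALD1 (AT2G13810), a gene with no counts in WT at 0 h, at its bound of at least 12.3-fold higher (3 counts per library). The rise may rest on 1 library. Without hy5 0 h replicate 3 the median was 0.36, 2 of 17 members were called and the list adjusted p was 0.0439. That p value was adjusted over the 25 lists of this comparison only, so it is not comparable with the other adjusted list p values. The mean log2 CPM of the list was 1.02, 1.17 and 0.90 in WT and 1.5, 1.58 and 3.86 in hy5, and the touch and wounding list stood at 4.52 in that library against 2.57 and 2.63 in the other hy5 libraries. Whether an infection, handling of the seedlings or the mutation raised it was not tested.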

How the results depend on the processing

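Alternatives chosen after the data were seen are named above, and the others were planned. With RLE size factors, with the filter of CPM at least 1 in at least 3 samples and with the replicate number as a block, all 22 counts stayed within 1.5 times. With the block the count for WT at 1 h was 1030, and it ended 41 of the calls of named genes and 0 of the list calls. As a hint from the data, 8 of 36 libraries correlated best with their own number, and every same-number correlation was over 0.1 in 7 of 66 pairs of groups, against 5.5 for numbers matched at random. Among the 7 are 0 and 1 h in hy5 and in pif457, where a fit of the 2 groups with the block gave 2324 and 25 genes. In what follows the cause was not tested. The main fit shares 1 spread per gene over 12 groups, and smaller fits use fewer samples and their own spread. Counts fell from 2143 to 13 for pif457 and rose from 2355 to 6634 for hy5 pif457 at 8 h. Main-fit p values may be too small for groups of wide spread and too large for others. Depth alone was not varied.

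In fits of only the groups compared, the counts were 329 for WT at 1 h, 497 for hy5 at 8 h, 0 for pif457 at 1 h by edgeR (1533 at unadjusted p under 0.05 in the full fit, and 114 with DESeq2), 13 for pif457 at 8 h, 270 and 6634 for hy5 pif457 at 1 and 8 h, 986 for WT at 8 h against 1 h, and 261 for hy5 and 8 for pif457 against WT at 0 h. For response differences they were 23 for hy5 at 8 h, 124 for pif457 at 8 h, 4492 for hy5 pif457 at 8 h, 1954 for hy5 pif457 minus pif457 at 8 h and 11 for the departure from additivity at 8 h. DESeq2 gave 114 for pif457 and 92 for hy5 pif457 at 1 h, 38 for pif457 against WT at 0 h, and for response differences 38 for hy5 at 1 h, 624 for hy5 at 8 h, 1150 for pif457 at 8 h and 2127 for additivity at 8 h. Without a filter on low counts 28 genes were called for pif457 at 1 h and 197 for the hy5 difference at 8 h.

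With the root marker score as a covariate the counts were 665 for pif457 at 8 h, 985 for hy5 pif457 at 8 h, 1 for the hy5 difference at 1 h, 131 for it at 8 h, 160 for pif457 at 8 h, 462 for hy5 pif457 minus pif457 at 8 h and 4 for additivity at 8 h. Without rRNA and organelle genes the hy5 difference at 8 h was 215. Without the 12 rRNA-rich libraries the counts were 738 for WT at 1 h, 16 for pif457 at 1 h, 1353 for hy5 against WT at 0 h and 123 for the hy5 difference at 8 h.

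Leaving out each library in turn gave ranges of 509 to 2484 for WT at 1 h, 2096 to 4727 for WT at 8 h, 898 to 1984 for hy5 at 1 h, 1383 to 1649 for hy5 at 8 h, 6 to 23 for pif457 at 1 h, 484 to 4235 for pif457 at 8 h, 13 to 21 for hy5 pif457 at 1 h, 723 to 2343 for hy5 pif457 at 8 h and 979 to 2003 for WT at 8 h against 1 h. Against WT at 0 h the ranges were 676 to 3129 for hy5, 13 to 153 for pif457 and 523 to 2670 for hy5 pif457. For response differences they were 0 to 1 for hy5 at 1 h, 80 to 644 for hy5 at 8 h, 151 to 184 for pif457 at 1 h, 261 to 2289 for pif457 at 8 h, 148 to 217 for hy5 pif457 at 1 h, 1122 to 4052 for it at 8 h, 2096 to 6189 for hy5 pif457 minus pif457 at 8 h and 5 to 3325 for additivity at 8 h.

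The root marker covariate ended 228 named gene calls (755 kept) and 43 list calls (179 kept). Fits of only the groups compared ended 333 gene calls (649 kept). Directions that turned were few. FRK1 (AT2G19190) in hy5 at 1 h was at 0.097 without hy5 0 h replicate 3, and between -3.51 and 0.097 over the left-out libraries. With the root marker score as a covariate ARR3 (AT1G59940) was at 0.676 for hy5 pif457 minus pif457 at 8 h and 0.762 for additivity at 8 h, and EXPA18 (AT1G62980) at 0.059 for the former. In the same fit the root tissue marker median was 0.011 in hy5 at 1 h, -0.029 in hy5 pif457 at 8 h, -0.016 in hy5 pif457 against WT at 0 h and -0.006 for hy5 pif457 minus pif457 at 8 h, the photosynthesis median 0.037 for the pif457 difference at 8 h and -0.20 for additivity at 8 h, and the stomatal median -0.065 for additivity at 8 h. The markers make up the score, so their own medians near 0 follow from that fit. With an estimated correlation, 46 list calls were kept and 183 were not.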

Other observations

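The glucosinolate list and its test in hy5 were chosen with the WT and hy5 values seen, and MRD1's neighbour HEI10 with its own values seen. The tests in pif457 and hy5 pif457 were set before their results. List p values here were adjusted over the 8 shade responses only, so they are not comparable with other lists. Genes of aliphatic glucosinolate synthesis fell together in WT at 8 h, with 21 of 22 lower (median -1.63). Camera gave adjusted p = 1.99e-19, and 0.0321 with an estimated correlation. IPMI1 (-2.51 ± 0.26) and BCAT4 (-2.04 ± 0.32) act in methionine chain elongation, and MYB29 (-2.14 ± 0.37) regulates the pathway. In hy5 20 were lower (median -1.41; adjusted p = 1.02e-20, and 0.0321 with an estimated correlation). At 1 h edgeR called 0 members in each genotype, with 1, 4, 0 and 0 at unadjusted p under 0.05 in WT, hy5, pif457 and hy5 pif457. The list test at 1 h passed with the preset correlation alone in hy5 (median -0.30; adjusted p = 0.00595; adjusted p = 0.592 with an estimated correlation) and hy5 pif457 (median -0.13; adjusted p = 0.0497; adjusted p = 0.691).

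MRD1 stood at 32.9 ± 3.21 CPM in WT at 0 h, 0.115 ± 0.118 in hy5, 0.0503 ± 0.0436 in pif457 and 13.7 ± 1.78 in hy5 pif457. HEI10 (AT1G53490), a meiotic gene beside it in TAIR10.1, stood at 6.50 ± 0.534, 1.75 ± 0.0866, 1.85 ± 0.281 and 4.47 ± 0.231 CPM in the same order. Both genes were thus low in hy5 and pif457 but not to the same degree in hy5 pif457, and whether the lines carry different alleles at this locus was not tested. Some other genes called in pif457 at 0 h differed from WT in every mutant. In the same order, LBD26 (AT3G27940) stood at 4.07, 0.742, 0.213 and 0.223 CPM and AT1G75945 at 0.0662, 4.56, 4.75 and 5.78 CPM. ARP9 was near WT in hy5, at 14.2, 16, 37.9 and 24.9 CPM. Whether such genes mark differences between the lines beyond the named mutations was not tested. PAO3, which was lower in pif457 at 0 h (-0.51 ± 0.08), is a neighbour of PIF5 in TAIR10.1.

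The fall of the glucosinolate genes may be a part of the shade response that depends on the PIFs. In hy5 90.9% were lower, which tests nothing, as the list was chosen with this seen. In pif457 13.6% were lower (3 members, median -0.52, camera adjusted p = 1.86e-07, and adjusted p = 0.262 with an estimated correlation). In hy5 pif457 36.4% were lower (8 members, median -0.64, camera adjusted p = 1.44e-06, and adjusted p = 0.262 with an estimated correlation). Both shares lie between the bounds of 10% and 50% set in advance, so this prediction decides neither way. Tested against the WT response at 8 h, 7 members in pif457 and 8 in hy5 pif457 had a more positive response, and 0 a more negative one. In hy5 edgeR called 0 members in either direction. Choosing the list with WT and hy5 seen favours stronger falls there. With the root marker score as a covariate edgeR called 0 members lower in pif457 (6 at unadjusted p under 0.05, median -0.33). In hy5 pif457 that fit called 10 lower (19 at unadjusted p under 0.05, median -0.86). The pif457 libraries at 8 h are among the rRNA-rich ones, so a batch is not excluded.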
